A study of Mus musculus with 9 samples.

How the data were processed

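RNA was extracted from c-Kit+ bone marrow cells, and poly(A) RNA was made into strand-marked libraries and sequenced as read pairs, per the labels' protocols. Reads were trimmed, aligned and assembled with tools that include cutadapt 1.9, HISAT2 2.2.1 and StringTie 2.1.6 on GRCm39, per the submitters' processing notes, which give no role or order. The notes also name DESeq2 and edgeR without a version or role. The annotation release, the strand setting of the counting and any filters are not given in the sources used here. The authors deposited FPKM values per gene and library, in which the fragments of a gene are divided by its transcript length and by the library's mapped total. In the same table they deposited an estimated count per gene and library, which is not normalized. The estimated counts are whole numbers, but their lowest values above 0 gather at 4: of 891 values, 14 equal 4, while 0 equal 1 and 1 each equal 2 and 3. One sequenced fragment is therefore taken to be worth about 4 counts, and the counts are treated as estimates.

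The table analysed here held 99 genes, all with a symbol and sorted by Ensembl identifier from ENSMUSG00000000001 to ENSMUSG00000000673. These are a small part of the genome, and every count of changed genes refers to them. The sum of their counts is about 0.5% of a library, so it is not the depth. The depth was recovered from the ratio of count to FPKM, which differs between libraries by the same factor for each gene. It was taken from 61 genes with at least 200 counts in every library, and 100% of their values lay within 1% of the fitted ratio. The absolute scale came from 6 genes with a single annotated transcript, whose lengths were read from a GRCm38 annotation. No coordinate was taken from that annotation. Implied totals were 76613082, 84833060 and 80781267 counts in WT replicates 1 to 3, 88187017, 79720194 and 88325760 in NC, and 88424059, 80341629 and 82289705 in NPC.

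Libraries were grouped by the codes in their titles and genotype labels. The 3 contrasts were NC against WT, NPC against NC and NPC against WT. The test set before the data were examined was limma on log2(FPKM + 1), with edgeR to be used if the table held counts. It did, so edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) was run on the estimated counts, already whole numbers, in a single fit of all 9 libraries with group means and no block. The implied depth served as library size. Genes with FPKM of at least 1 in at least 3 libraries were tested (62 of 99). P-values were two-sided, adjusted by the Benjamini-Hochberg method over the tested genes, with a threshold of 0.05. Standard errors were derived from the fold change and its F statistic, and confidence intervals are at 95%. In simulated data for NC against WT with 62 genes and 15 changed genes (50 simulations), the test called 89.2% of genes changed by 0.25 on the log2 scale, 99.2% of those changed by 0.5 and 100% of those changed by 1. It called 1.11% of the other genes.

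The genes named were set by a rule fixed before the data were examined. For each contrast it took genes with a mean FPKM of at least 5 in either group that passed the threshold and whose groups did not overlap, up to the 10 largest rises and 10 largest falls, and up to 4 members of each fixed gene list. Gene models without a symbol and those named Gm or Rik with a number were left out of naming, and Gm2a is not such a model. Genes named outside the rule are marked in the text. In all, 29 gene lists were fixed, for blood cell types, signalling, proliferation, metabolism, interferon, adhesion and other themes. No list had the 5 tested genes required, so no gene list test was run. Among the 8 lists with a member were those of T and NK cells (Lck), DNA replication (Cdc45), interferon-stimulated genes (Mx1), immediate-early genes (Klf6), glycolysis and hypoxia (Hk2), oxidative phosphorylation (Cox5a), and adhesion and homing (Itga5 and Itgb2). The other 21 lists had no member in the table. Piezo1 was not analysed here. Some genes that the rule takes are not reported here, though counts of genes include them.

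Alternatives covered the pseudocount (0.1 in place of 1, in limma 3.58.1), filters on low values, median of ratios scaling, quantile normalization, the libraries in the fit, array weights, robust moderation, the replicate number as a block and leaving out each library. Quantile normalization used the 62 tested genes alone, so each rank took the same value in every library. The limma test on log2(FPKM + 1) set in advance became an alternative once counts were used. Alternatives chosen after seeing the data were DESeq2 1.42.0, TMM factors, the summed counts of the table as library size, counts divided by 4, the average of NC replicates 2 and 3, and leaving out Mx1. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.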

Results

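Gene expression was measured by poly(A) RNA sequencing in c-Kit+ cells sorted from mouse bone marrow, a fraction that holds blood stem and progenitor cells. The series describes control mice, mice with chronic myelomonocytic leukaemia (CMML) and CMML mice with a conditional knockout of Piezo1, which encodes a mechanically gated cation channel. The 9 libraries fell into 3 groups of 3, labelled WT, NC and NPC. The labels do not spell out these codes. Reading NC as CMML and NPC as CMML with the Piezo1 knockout follows the order and letters of the codes, so the groups are called NC and NPC here. The labels do not say that the libraries of a group came from separate animals, and p-values then measure the spread between these libraries, which may be technical. The table analysed here held 99 genes, of which 62 reached the expression minimum and were tested. Piezo1 was not analysed here, so the knockout could not be used to check the labels.

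The depth implied by the ratio of estimated count to FPKM ran from 76613082 counts in WT replicate 1 to 88424059 in NPC replicate 1, a ratio of 1.15. The 99 genes took 387039 to 469541 counts per library. Pearson correlations of log2(FPKM + 1) across the 62 tested genes, which are not independent replicates, lay between 0.998 and 0.999 for pairs within a group and between 0.972 and 0.999 for pairs from different groups. The leading principal component held 87.3% of the variance and placed the WT libraries at -1.65 to -1.53, the NC libraries at 0.32 to 0.81 and the NPC libraries at 0.87 to 1.17. In a chi-square test of counts for pairs within a group, NC replicates 2 and 3 differed least. Their deposited counts differed by more than counting noise (chi-square over degrees of freedom 4.69), but not once 4 counts were taken as 1 fragment (1.17). On that scale NC replicates 1 and 3 were also near counting noise (1.34, chi-square test p = 0.0383), while NC replicates 1 and 2 differed more (2.22). All 3 NC libraries were kept as replicates because the count scale is inferred. Counts of changed genes with NC replicates 2 and 3 averaged into 1 library are given beside the NC comparisons.

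If the codes are read as above, the comparison of NC with WT asked how c-Kit+ cells of CMML mice differed from control cells. Mx1, an interferon-induced GTPase, had the largest rise, from 2.60 ± 0.0213 FPKM in WT to 7.93 ± 0.898 FPKM in NC (SD, n = 3 each), a 3.04-fold increase. Gm2a, which encodes the GM2 ganglioside activator of lysosomes, rose 1.55-fold from 20.0 ± 0.529 to 30.9 ± 0.668 FPKM. The leukocyte integrin genes Itgb2l and Itgb2 (CD18) rose 1.29-fold and 1.21-fold, and Hk2, which encodes hexokinase 2 of glycolysis, rose 1.25-fold. Sdhd, which encodes a subunit of respiratory complex II, fell from 113.7 ± 3.20 to 97.6 ± 1.29 FPKM, or 0.86 times the WT level.

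In total 32 of the 62 genes changed, 17 higher and 15 lower in NC, and 35 had an unadjusted p under 0.05 (edgeR quasi-likelihood test). Most changes were small, with a median absolute log2 fold change of 0.25 among changed genes. Changes above 1.5-fold were found for 5 genes, namely Mx1, Gm2a, Tamalin, Sema4f and Haao. The last 3 had FPKM under 5 and were chosen after their values were seen. Tamalin rose by 1.25 ± 0.14 (log2 fold change ± SE), Sema4f by 0.93 ± 0.14 and Haao by 0.78 ± 0.08. The log2 fold change of Mx1 was 1.61 ± 0.07 (SE; 95% confidence interval 1.45 to 1.76; edgeR adjusted p = 9.28e-20). That of Gm2a was 0.63 ± 0.04 (0.55 to 0.70; edgeR adjusted p = 8.85e-17), and that of Sdhd was -0.22 ± 0.04 (-0.29 to -0.15; edgeR adjusted p = 4.17e-06). The 3 libraries of each group did not overlap for 36 of the 62 genes (58.1%), against 10% by chance.

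Among the gene lists set in advance, 8 had a member in the table, with 9 members in all. Of these 9 genes, 5 rose and 2 fell. The counts were the same when p was adjusted within each list. That is no separate check, since a list had 1 member, or 2 for adhesion and homing. The rises were Mx1 of the interferon-stimulated genes, Hk2 of the glycolysis and hypoxia genes, Klf6 of the immediate-early genes, Lck of the T and NK cell genes and Itgb2 of the adhesion and homing genes. Klf6, a zinc-finger transcription factor, rose by 0.32 ± 0.04 (log2 fold change ± SE), from 42.0 ± 1.13 to 52.3 ± 0.905 FPKM. Lck, a T-cell kinase gene, rose by 0.52 ± 0.09, from 3.30 ± 0.292 to 4.72 ± 0.272 FPKM. Itga5, which encodes a fibronectin receptor subunit and stands in the same adhesion list as Itgb2, fell by 0.12 ± 0.04. Cox5a, a subunit gene of respiratory complex IV, fell by 0.12 ± 0.05. Cdc45, a DNA replication gene, did not pass, with a log2 fold change of 0.06 ± 0.04. Under quantile normalization it passed as a fall, at -0.12 (limma adjusted p = 0.0265). Only the 62 tested genes, 32 of them changed, were normalized there, and a rank can shift because other genes changed.

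The other genes taken by the naming rule rose or fell by smaller amounts. Septin1 rose by 0.31 ± 0.04 (log2 fold change ± SE), Acvr1b, an activin receptor gene, by 0.26 ± 0.06, Scpep1 by 0.18 ± 0.06 and Gnai3, a G-protein subunit gene, by 0.13 ± 0.04. Dlat, which encodes a component of pyruvate dehydrogenase, fell by 0.21 ± 0.04 from 16.7 ± 0.316 to 14.4 ± 0.344 FPKM. Gmpr fell by 0.25 ± 0.08, Tbrg4 by 0.20 ± 0.04, Narf by 0.20 ± 0.04, Myo18a by 0.17 ± 0.04, Hnrnpd by 0.14 ± 0.04 and Slfn4 by 0.11 ± 0.04.

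With NC replicates 2 and 3 averaged, 28 genes changed, 17 higher and 11 lower, and Cox5a and Slfn4 no longer passed (edgeR adjusted p = 0.0749 for both). The split of 17 higher and 15 lower became 12 and 18 under quantile normalization, where Itga5, Lck, Acvr1b, Gnai3 and Cox5a did not pass. A gene moves there only by changing rank, and Itga5 was at 0. Single libraries also decided small falls and rises: Itga5 did not pass without WT replicate 1 or NC replicate 1, Scpep1, Gmpr and Slfn4 without WT replicate 2 or NC replicate 2, and Cox5a without WT replicate 1, WT replicate 2, NC replicate 2 or NPC replicate 2. Slfn4 did not pass with DESeq2 either, nor Cox5a with DESeq2, TMM factors or limma at either pseudocount.

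**Figure D1:**
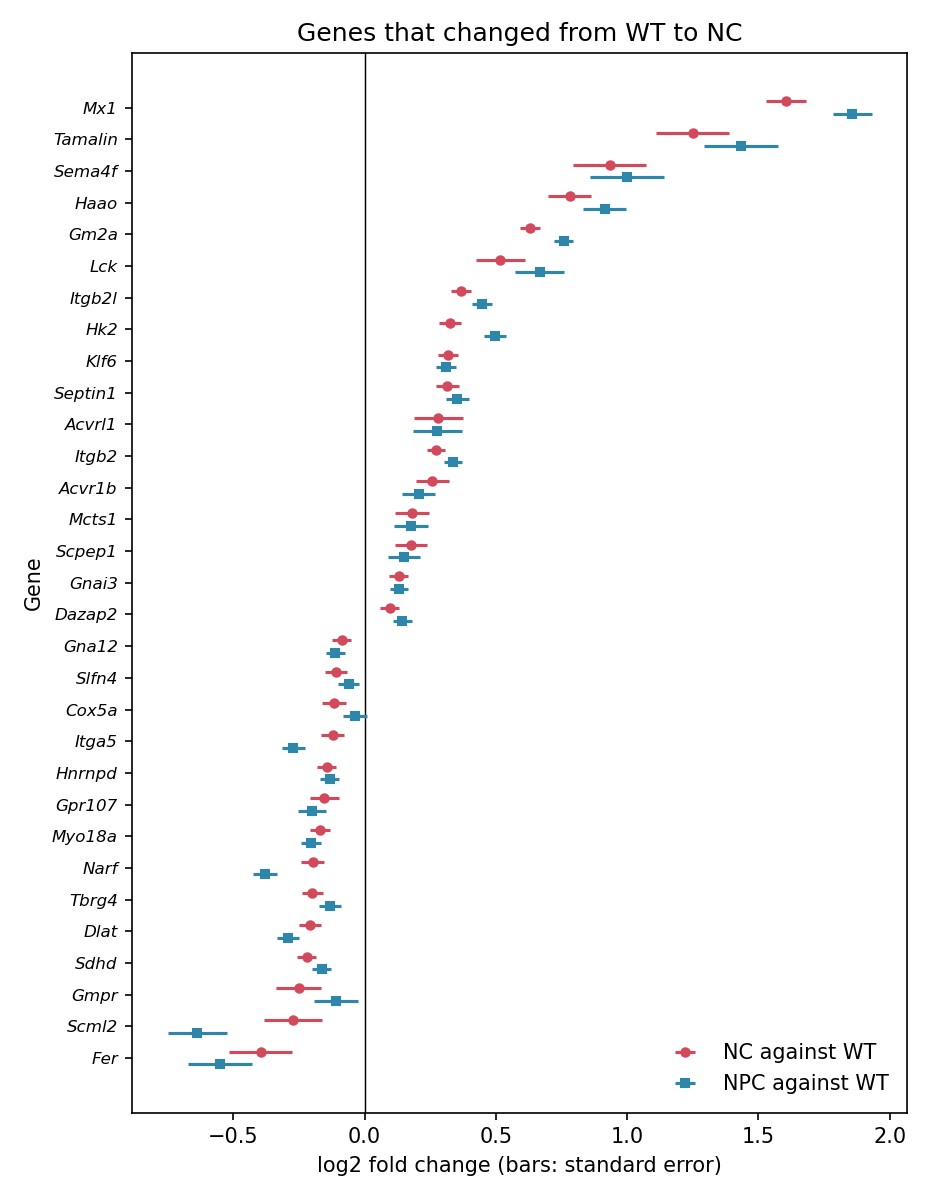
Log2 fold changes (x axis) of 31 of the 32 genes that changed from WT to NC (y axis), with circles for NC against WT and squares for NPC against WT, and bars for the standard error, n = 3 libraries per group. Mx1 stands highest, at 1.61 in NC and 1.86 in NPC, followed by Tamalin, at 1.25 in NC and 1.43 in NPC.

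If the codes are read as above, the comparison of NPC with NC asked how expression differed with the Piezo1 knockout within the CMML background. Changes were few and below 1.5-fold. Hk2 was 1.13-fold higher in NPC, at 14.5 ± 0.596 FPKM against 12.9 ± 0.309 FPKM in NC (SD, n = 3 each), and Mx1 was 1.19-fold higher, at 9.46 ± 0.222 against 7.93 ± 0.898 FPKM. Mnt, which encodes a Max-binding repressor that opposes Myc, was 1.12-fold higher, and Gm2a 1.09-fold higher. Narf and Itga5 were lower, at 0.88 and 0.90 times the NC level.

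In total 9 of the 62 genes changed, 4 higher and 5 lower in NPC, and 16 had an unadjusted p under 0.05 (edgeR quasi-likelihood test). The log2 fold change was 0.17 ± 0.04 for Hk2 (SE; 95% confidence interval 0.09 to 0.26; edgeR adjusted p = 0.00822), 0.25 ± 0.07 for Mx1 (0.11 to 0.39; edgeR adjusted p = 0.0126) and 0.16 ± 0.05 for Mnt (0.07 to 0.26; edgeR adjusted p = 0.0126). It was -0.18 ± 0.04 for Narf and -0.15 ± 0.04 for Itga5. The remaining falls were Cav2, which encodes caveolin 2, at -0.48 ± 0.14, Scml2 at -0.37 ± 0.11 and Krit1 at -0.18 ± 0.05. These 3 genes lay under 5 FPKM and were chosen after their values were seen. Of the 9 listed genes, 2 were higher (Mx1 and Hk2) and 1 lower (Itga5). Adjusting within each list, of 1 or 2 members, gave the same counts and is no separate check. Among those that did not pass, Lck had a log2 fold change of 0.15 ± 0.09, Cox5a 0.08 ± 0.05, Itgb2 0.06 ± 0.03 (0.10 with edgeR adjusted p = 0.0328 under median of ratios scaling), Cdc45 0.05 ± 0.04 and Klf6 -0.01 ± 0.04. The groups did not overlap for 17 of the 62 genes (27.4%), against 10% by chance.

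These calls depended on which libraries were included. Without NC replicate 2 or without NPC replicate 3, 3 genes changed, without NPC replicate 2, 4 genes, and without NPC replicate 1, 15 genes. Hk2 and Narf passed whichever library was left out, whereas Mx1 did not pass without NC replicate 2 or NPC replicate 2, Gm2a and Mnt without NC replicate 2, NC replicate 3 or NPC replicate 3, and Itga5 when any of these 4 libraries was left out. With NC replicates 2 and 3 averaged, 4 genes changed, 1 higher and 3 lower, with Hk2 and Narf still past the threshold and Mx1, Mnt, Gm2a and Itga5 not (edgeR adjusted p = 0.0622 for each). Under quantile normalization 5 genes changed, 3 higher and 2 lower, and Mx1, Mnt and Narf did not pass.

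**Figure D2:**
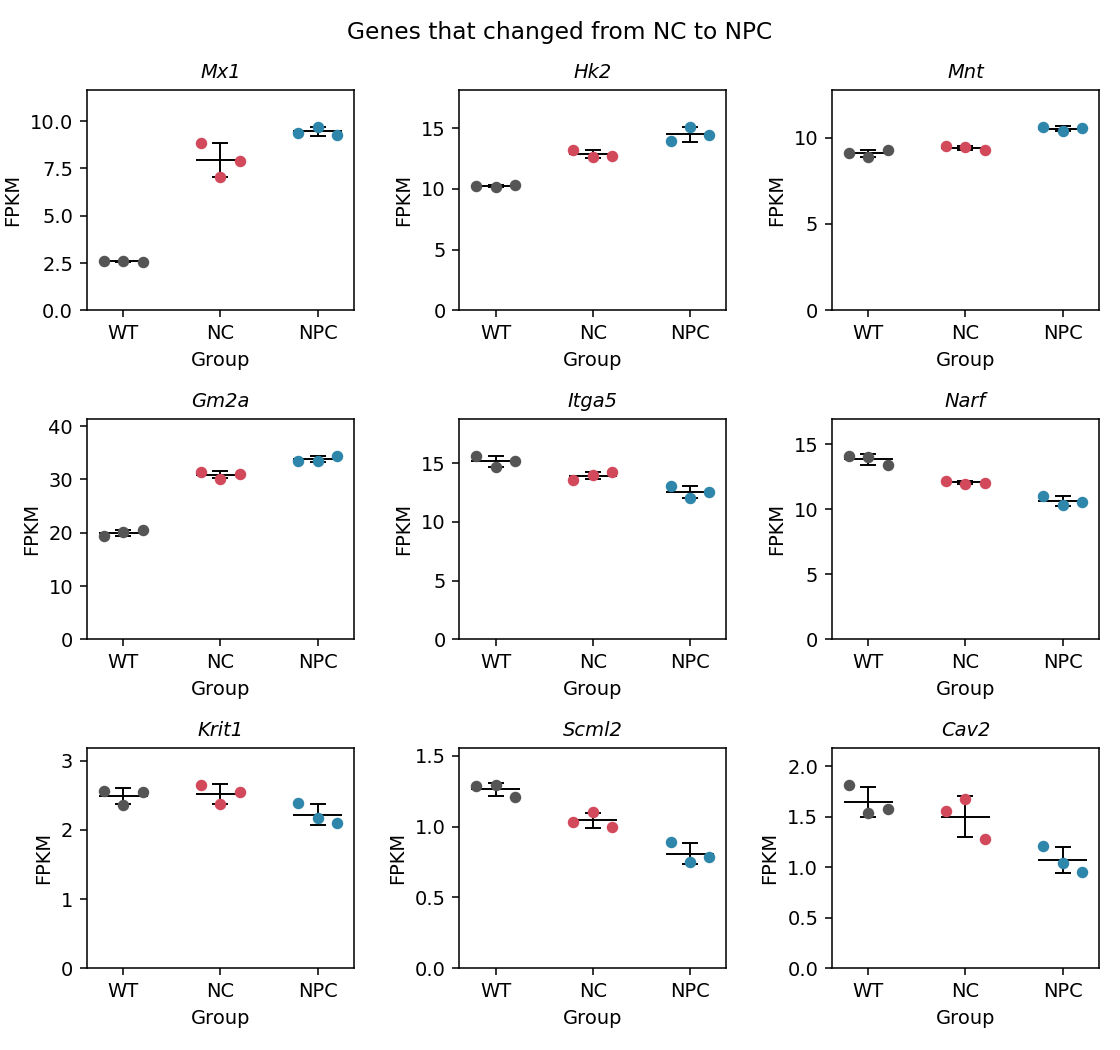
FPKM (y axis, from 0) of the 9 genes that changed from NC to NPC, in each library of the WT, NC and NPC groups (x axis), with 1 point per library, a line at the mean and bars for the SD, n = 3. Mx1 averaged 2.60 FPKM in WT, 7.93 in NC and 9.46 in NPC, while Narf averaged 13.9, 12.1 and 10.7 FPKM.

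NPC was also compared with WT, where 40 of the 62 genes changed, 21 higher and 19 lower, and 43 had an unadjusted p under 0.05 (edgeR quasi-likelihood test). Mx1 was 3.62-fold higher, Gm2a 1.69-fold, Lck 1.59-fold, Hk2 1.41-fold and Itgb2l 1.36-fold. Narf was at 0.77 times the WT level (10.7 ± 0.357 against 13.9 ± 0.413 FPKM; SD, n = 3 each) and Itga5 at 0.83. Of the 9 listed genes, 6 were higher and 1 lower, with the same counts adjusted within each list, of 1 or 2 members, which is no separate check. Cdc45 was among the 6, at 0.11 ± 0.04 (log2 fold change ± SE; edgeR adjusted p = 0.03), but had a log2 fold change of -0.062 under quantile normalization, and did not pass there, without WT replicate 1, WT replicate 3 or NPC replicate 3, with DESeq2 or with the summed counts of the table as library size. Further rises were found for Septin1 (0.35 ± 0.04), Itgb2 (0.34 ± 0.03), Klf6 (0.31 ± 0.04), Mnt (0.21 ± 0.05) and Acvr1b (0.21 ± 0.06). Further falls were found for Dlat (-0.29 ± 0.04), Myo18a (-0.20 ± 0.04), Sdhd (-0.16 ± 0.04), Trappc10 (-0.14 ± 0.04), Hnrnpd (-0.13 ± 0.04), Tbrg4 (-0.13 ± 0.04, not passing without NPC replicate 2) and Gna12 (-0.11 ± 0.04). Trappc10 and Gna12 did not pass under quantile normalization (limma adjusted p = 0.162 and 0.126). Cox5a did not pass, at -0.04 ± 0.05. The split of 21 higher and 19 lower became 15 and 24 under quantile normalization and 18 and 26 with the summed counts of the table as library size.

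Of the genes that changed against WT, 29 did so in both NC and NPC, all 29 in the same direction, 17 higher and 12 lower. Independent lists would share 5.76 higher and 4.60 lower genes. Both comparisons used the same WT libraries, and 100 simulations of groups with no change gave 0 shared genes. With no change put in, hardly any gene can pass. This 0 therefore does not show how much of the overlap comes from the shared libraries. The covariance of both sets of fold changes was 0.150, against a simulated mean of 0.00243 from the shared WT libraries, a difference of 0.147. The 3 WT libraries could not be divided into sets of several libraries each, so part of the excess over independent lists may come from the shared controls.

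A further comparison asked whether the changes from NC to NPC went back toward WT. No gene changed in opposite directions in the 2 steps, where independent lists would give 2.34 genes. By contrast 6 genes changed in the same direction in both steps: Mx1, Gm2a and Hk2 rose in each, and Narf, Itga5 and Scml2 fell in each, where independent lists would give 1.10 higher and 1.21 lower genes. Of the 32 genes that changed from WT to NC, 21 (65.6%) had the same sign from NC to NPC. Among the 30 tested genes that had not changed, the same sign was not the more frequent. Across the 62 genes, which are not independent replicates, the covariance of the 2 sets of log2 fold changes was 0.0240. The shared NC libraries alone gave a mean of -0.00237 in 100 simulations, with a highest value of 0.000156, so the difference was 0.0264. The correlation across genes was 0.55 (Pearson) and 0.46 (Spearman), and without Mx1 the covariance was 0.0176. With no expression minimum the covariance was -0.379 over all 99 genes, and 0.0240 over the 62 tested genes of that fit. Quantile normalization, by rank among the 62 tested genes, gave 2 genes in the same and 2 in opposite directions. Averaging NC replicates 2 and 3 gave 2 and 0. The count in the same direction was 2 without NC replicate 2 and 3 without NC replicate 3, NPC replicate 2 or NPC replicate 3.

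**Figure D3:**
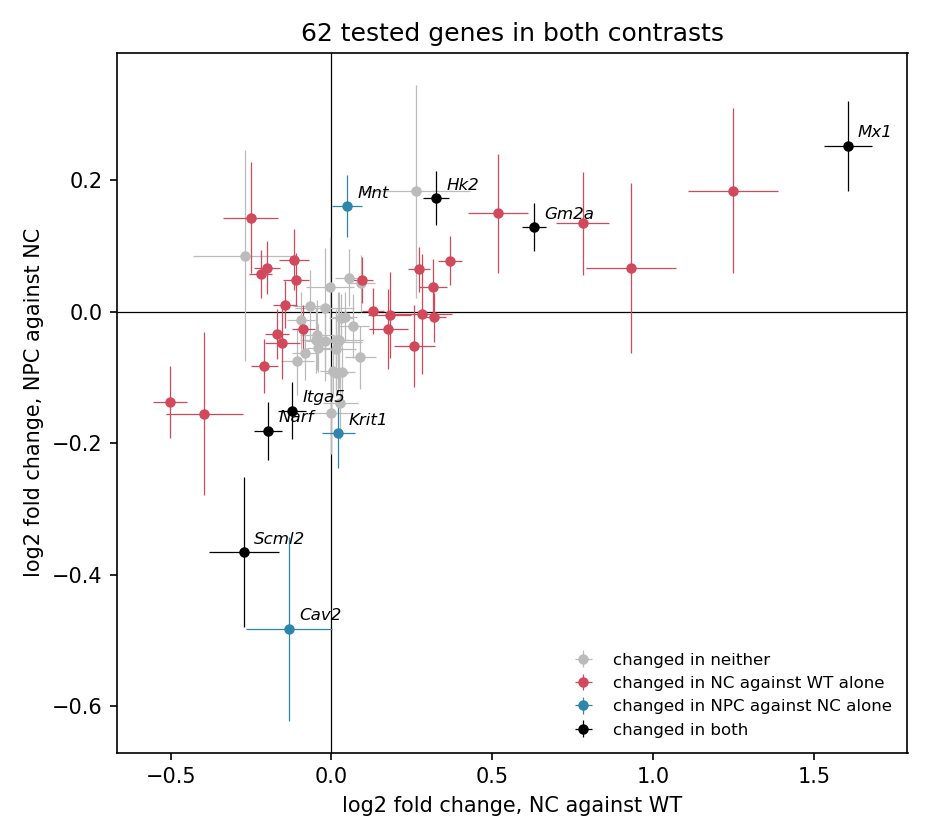
Log2 fold change of NPC against NC (y axis) plotted on that of NC against WT (x axis) for the 62 tested genes, with bars for the standard error, n = 3 libraries per group. Genes that changed in both steps are black, and all 6 lie in the upper right or the lower left.

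Some of the genes named above lie as follows on GRCm39, as the table gives them. Mx1 (ENSMUSG00000000386) lies on chromosome 16 from 97248235 to 97264107 and Itgb2l (ENSMUSG00000000157) on chromosome 16 from 96223488 to 96244819. Gm2a (ENSMUSG00000000594) lies on chromosome 11 from 54988941 to 55003855 and Narf (ENSMUSG00000000056) on chromosome 11 from 121128079 to 121146682. Hk2 (ENSMUSG00000000628) lies on chromosome 6 from 82702006 to 82751435 and Itga5 (ENSMUSG00000000555) on chromosome 15 from 103252713 to 103275190. Mx1 has a close relative, Mx2, and Slfn4 belongs to a family of similar genes. How reads that match several family members were assigned is not given in the sources used here, so the levels of Mx1 and Slfn4 are uncertain to that extent.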

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

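The tests over other groupings of the libraries in this part are to be read as chosen after the results were seen. The 37 genes below the expression minimum were left out of the comparisons, and with no minimum 12 of them passed the threshold against WT. From WT to NC the log2 fold changes were 1.78 for Rem1, 1.68 for H19, 1.25 for Adora3, 0.76 for Slc22a18 and 0.50 for Cdh1, and -0.69 for Pih1d2, -0.84 for Axin2 and -0.84 for Alox12. From WT to NPC they were 2.12 for H19, 2.08 for Cttnbp2, 1.08 for Adora3, 0.77 for Slc22a18 and 0.49 for Cdh1, and -0.52 for Drp2, -0.70 for Pparg, -0.75 for Alox12, -0.89 for Axin2, -0.94 for Pih1d2 and -3.16 for Egfl6. In both contrasts 7 of the genes passed. Several rest on few fragments, where 1 fragment is worth about 4 counts. Per WT library, H19 had 3 to 13 counts, Rem1 0 to 14 and Cttnbp2 4 to 7. Egfl6 had 0 to 5 counts per NPC library. From WT to NC the groups overlapped for Cdh1.

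The number of genes that changed was also counted for other groupings of the same 6 libraries. For NC against WT the deposited groups gave 32 genes and the highest of the other groupings gave 0. For NPC against NC these values were 9 and 0, and for NPC against WT 40 and 0. In each contrast 1 of the 10 possible groupings, the deposited groups themselves, gave as many genes. With 10 groupings the share cannot go under 0.05.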

How the results depend on the processing

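Over 24 alternatives, 32 of the 49 calls on named genes were kept in each, 17 were lost in at least 1, and 2 of the 10 named values that did not pass did so in an alternative. Counts stayed within 1.5 times the reported ones except as follows, and the cause was not tested unless given. Quantile normalization with limma gave 5 genes for NPC against NC, 2 genes in opposite and 2 in the same direction in the 2 steps, and a covariance of 0.0127. It reversed Cdc45, to -0.12 for NC against WT, where it passed as a fall, and -0.062 for NPC against WT. A rank among the 62 tested genes can shift because other genes changed, so this reversal does not decide the direction of Cdc45. The covariance was 0.0149 with limma on log2(FPKM + 1) and 0.0154 with array weights, both on a log scale that shrinks low genes. With no filter it was -0.379 over 99 genes but 0.0240 over the 62 tested genes of that fit, so the low genes reverse it. NC replicates 2 and 3 averaged gave 4 genes for NPC against NC and 2 in the same direction. Leaving out each library gave 23 to 34 genes for NC against WT, 3 to 15 for NPC against NC (3 without NC replicate 2 or NPC replicate 3, 4 without NPC replicate 2, 15 without NPC replicate 1), 35 to 45 for NPC against WT, 2 to 9 genes in the same direction, 0 to 0 in opposite directions, and covariances of 0.0193 to 0.0297. With the replicate number as a block, 31, 9 and 40 genes changed (32, 9 and 40 without it), with 0 opposite, 6 same and a covariance of 0.0242. Same-numbered libraries had correlations of -0.25 to 0.31 in their deviations, and differently numbered ones -0.34 to 0.29. With their own number 4 of 9 libraries correlated best, so no pairing by number was detected. With 3 libraries per group, pairing or a shared batch cannot be excluded. Gene list tests (camera, also with an estimated correlation, and fry) and Piezo1 values were not run under any alternative, since no list had 5 tested genes and Piezo1 was not analysed here.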

Other observations

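The tests of explanations in this part were all chosen after the results were seen. Against WT, 11 genes passed in NPC that did not pass in NC, and 3 of them, Mnt, Cav2 and Krit1, also differed between NPC and NC. For the rest that difference did not pass (edgeR quasi-likelihood test). Among these, named after their values were seen, were Clec10a, a lectin gene of macrophages and dendritic cells, at 0.45 ± 0.17 from WT to NPC (log2 fold change ± SE) and 0.26 ± 0.17 from WT to NC, and Tspan32, a tetraspanin gene of blood cells, at 0.14 ± 0.04 and 0.09 ± 0.04. Ndufa9, a respiratory complex I gene, was at -0.11 ± 0.04 and -0.09 ± 0.04, and Atp5pb, an ATP synthase gene, at -0.10 ± 0.04 and -0.04 ± 0.04. Atp5pb overlaps Wdr77 on the opposite strand by 731 bp, so its level is uncertain.

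Mx1 was higher in NC and NPC than in WT. Library depth or scaling is argued against, since the lowest log2 fold change of Mx1 from WT to NC over the scalings was 1.184, under quantile normalization. Whether an interferon response raised Mx1 could not be tested, since Mx1 was the only member present of the 22 fixed interferon-stimulated genes. Slfn4 and Trim25 are both interferon-induced. From WT to NC Slfn4 passed as a small fall, at a log2 fold change of -0.11 (edgeR adjusted p = 0.0229), a call lost in 4 of 24 alternatives. Trim25 did not pass, at 0.03. Across both genes the median log2 fold change was -0.038, with upper 95% limits of -0.03 and 0.11. These genes were picked after their values were seen and so cannot decide the question. An interferon response stays open. A transgene or strain variant at the locus may also be the cause, since laboratory strains carry different Mx1 alleles. Of the tested genes within 2000000 bp 1 of 1 changed (Itgb2l), too few to decide. The Mx1 promoter also drives a common Cre transgene, but the labels name no Cre line. The check of neighbouring genes does not bear on a transgene elsewhere in the genome.

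Among the 32 genes that changed from WT to NC, 21 had the same sign from NC to NPC. Among the 30 tested genes that had not changed, the same sign was not the more frequent. The covariance over the 62 tested genes was positive, at 0.0240. With no expression minimum it was -0.379 over 99 genes. Quantile normalization, by rank among the 62 tested genes, gave 2 genes in the same and 2 in opposite directions. The shared NC libraries enter the 2 steps with opposite signs and so pull the covariance down, with a highest simulated value of 0.000156. They could not have given the observed 0.0240, and this tells nothing about other causes. No 1 library accounts for the positive covariance, since the lowest covariance with a library left out was 0.0193 (without NC replicate 2). A different mix of cell types in the sorted cells may be the cause and cannot be told apart from a change within cells, since 1 gene of the 11 cell type marker lists could be tested. The knockout, if NPC carries it, is a further open explanation, untested.

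NPC replicate 1 lay nearer the NC libraries than the other NPC libraries did. On a scale with 0 at the NC mean and 1 at the NPC mean, each library left out of its own mean, it lay at 0.368, NPC replicates 2 and 3 at 0.974 and 1.13, and NC replicates 1 to 3 at 0.311, -0.179 and 0.343. A swap with an NC library is argued against, since the highest count of changed genes in any regrouping of the 6 libraries was 0, against 9 for the deposited groups. Its correlation was 0.9989 with NC replicate 1 and 0.9986 with NC replicate 3, against 0.9981 with NPC replicate 2 and 0.9978 with NPC replicate 3. With NC replicate 2 it was 0.9980. A wrong label cannot be told apart from spread among NPC libraries, since 0.368 lies just above the NC range. Depth may also play a part and cannot be told apart: the 3 deepest libraries lay at 0.311 to 0.368, and deeper minus shallower libraries gave 0.505 within NC but -0.684 within NPC, with 1 library on a side in each.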
